A study of Homo sapiens with 8 samples.

How the data were processed

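RNA was measured by poly(A)-selected RNA sequencing in 8 libraries from 2 human thyroid cancer cell lines, BCPAP and CAL-62. Cells of each line were treated with THZ1 at 100 nM for 6 h or with the vehicle DMSO, with 2 replicate libraries in each of the 4 groups. Per the labels' protocols, RNA was isolated with TRIzol, selected with oligo(dT) and ligated to adaptors, and a sequencing company built the libraries. The lines were grown in different media with different amounts of serum, so line and medium cannot be told apart. The labels do not say whether the replicates came from separate cultures or days.

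The authors' deposited files hold 1 value per gene and library, in an RPKM-type unit (reads scaled to the length of the gene and to a library total). The unit was inferred from the values, because the files carry no header. The submitters' processing notes name Bowtie2, DESeq2 and the genome build hg19, without roles, versions or order; the gene annotation and the strand setting of the counting are not given in the sources used here. The BCPAP table lists 11900 genes and the one for CAL-62 lists 11513, of which 10698 are in both. In each table the lowest mean over that line's DMSO libraries was just above 1, whereas the mean over the THZ1 libraries went down to 0. Genes under a DMSO mean of 1 are therefore outside the tables, and a gene switched on by THZ1 from below that level could not be seen.

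Every deposited value was tested for whether it equals a whole read number divided by a whole gene length and by a library total. A whole length that fitted all values of a gene within 0.02 reads was found for 12712 of 12715 genes, so reads per gene could be recovered. The library totals behind the authors' RPKM-type values departed by at most 2.22% (BCPAP) and 2.11% (CAL-62) from being proportional to median-of-ratios size factors, and by up to 10.1% and 23.3% from being proportional to the sums of reads. The values are therefore scaled so that a typical gene is level between the libraries of a line, and a change in the total amount of mRNA per cell would not show in them. Reads in listed genes ranged from 16680749 to 19987389 per library, with a median of 399 to 730 reads per gene. At these depths counting error is small against the spread between replicates for most genes, though not for small RNA features with few reads. Replicate libraries of a group differed far beyond counting noise (chi-square over degrees of freedom 66.5 to 119.7), so none was counted as a repeated deposit.

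The plan had fixed a count test as the main test and a limma fit on log2 values as the fallback for normalized values. Because the files held normalized values, the fallback was used. limma 3.58.1 in R 4.3.3 was run with a mean-variance trend on log2(value + 1), on genes with a mean value of at least 1, with a separate mean for each of the 4 groups. All 8 libraries shared 1 estimate of the spread. Genes listed in 1 line only were fitted on that line's 4 libraries, and the variances were moderated together. P-values are two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. The contrasts were THZ1 against DMSO in each line, the difference of the responses, and the lines under DMSO. In 200 changed genes simulated on the real means, the BCPAP contrast, in a step of 10653 genes, called 18% of 2-fold changes, 68% of 4-fold changes and 90% of 8-fold changes. The CAL-62 contrast, in a step of 10652 genes, called 6%, 72% and 90%. In each, 2 unchanged genes were called. The simulated changes were placed only in genes with many reads, and noise was drawn independently for each library.

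The comparisons, the gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The lists hold genes of transcription kinases, immediate early genes, MAPK output, NF-κB and cytokines, YAP/TEAD and TGF-β targets, mesenchymal and epithelial genes, cell death and survival, p53 targets, DNA repair, S phase, G2/M, histones, stress responses, ribosomal proteins, energy metabolism, cholesterol, interferon and thyroid differentiation, 3 genes of interest to the study, and markers of blood, endothelial and fibroblast cells. There were 28 lists. A list with at least 5 tested members was tested with camera (limma), with a preset inter-gene correlation of 0.01 and, beside it, an estimated correlation, over both lines and their difference with 1 adjustment. With an estimated correlation the test rests on the few residual degrees of freedom of the 8 libraries. It has little power, so a list that does not pass it is left undecided. Named genes are, per comparison, the 5 largest falls and the 5 largest rises among called genes with a mean value of at least 5 and no overlap between the groups, then the top 2 called members of each list past the camera test. CDK7, CDK12, CDK13, MYC, PPP1R15A, SMG9 and KLF2 were always to be named. Other called members of the lists are named where few members were called, and those were chosen after their values were seen. Of the genes picked by the rule, 1 is not reported here.

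Symbols were matched to GENCODE release 29, and 11817 of 12715 matched, 920 of them through a synonym. That annotation is on another genome build than the files, so it was used only for gene type, exon number, GC content and host genes, and no coordinates are given. Alternatives were other scalings (median-of-ratios, upper quartile, sum of reads, ribosomal protein genes as reference, mitochondrially encoded genes as reference), no filter, a mean of at least 5, a pseudocount of 0.1, limma-voom on recovered reads of genes in both tables, fits on the compared libraries alone, the replicate number as a block, and leaving out each library. Random lists for comparison were matched on quintiles of length and mean level and drawn 10000 times. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps.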

Results

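Gene expression was profiled by poly(A)-selected RNA sequencing in BCPAP and CAL-62, established human thyroid carcinoma lines that the labels both call anaplastic. The study asked how the lines respond to THZ1, a covalent inhibitor of CDK7, the kinase of the general transcription factor TFIIH that phosphorylates RNA polymerase II. Cells received THZ1 at 100 nM or the vehicle DMSO for 6 h, with 2 libraries in each of the 4 groups. Reads in listed genes came to 18572596 and 18962899 in the BCPAP DMSO libraries and 18476063 and 19332138 in the BCPAP THZ1 libraries. They came to 18776857 and 19327016 in the CAL-62 DMSO libraries and 16680749 and 19987389 in the CAL-62 THZ1 libraries. Values below are RPKM-type values as mean ± SD (n = 2), changes are THZ1 minus DMSO in log2(value + 1), and adjusted p-values are from limma with Benjamini-Hochberg adjustment. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

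The libraries separated first by cell line. Within CAL-62 each library correlated best with the other of its treatment (r = 0.959 and 0.950), whereas within BCPAP each correlated best with the same-numbered library of the other treatment (r = 0.981 and 0.977). The first principal component of the genes in both tables held 55.0% of the variance and parted BCPAP from CAL-62. The second held 20.3% and placed both THZ1 libraries of each line below both DMSO libraries of that line, with a wider gap in CAL-62. The third held 15.2% and parted replicate number 1 from number 2 in all 4 groups, so changes are also given within each number where they matter. Mitochondrially encoded genes took 4.74% and 2.69% of reads in the BCPAP DMSO libraries and 5.07% and 3.38% after THZ1. In CAL-62 they took 6.26% and 3.74% under DMSO and 10.3% and 5.45% after THZ1.

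In the main fit, most of the genes called in CAL-62 after 6 h of THZ1 were lower, while the median change of all tested genes was 0.031. This majority did not hold with the replicate number as a block. Falls were ranked among called genes with a mean value of at least 5 and no overlap between the groups. Those that fell furthest included XBP1, the transcription factor of the unfolded protein response, and ZBED5, a zinc finger gene derived from a DNA transposon. The small nucleolar RNA SNORD81 was another. XBP1 fell from 59.0 ± 35.0 to 4.90 ± 1.52 (change -3.24, SE 0.42, limma adjusted p = 0.0166), and ZBED5 from 17.8 ± 1.69 to 1.17 ± 0.439 (change -3.13, SE 0.34, limma adjusted p = 0.0146). SNORD81 fell from 27.1 ± 7.79 to 2.71 ± 1.45 (change -2.95, SE 0.43, limma adjusted p = 0.019), and the uncharacterised gene LOC100509100 from 11.4 ± 0.939 to 0.625 ± 0.297 (change -2.95, SE 0.24, limma adjusted p = 0.009). SNORD44, another small nucleolar RNA, had 19 and 21 reads in the DMSO libraries and 0 in both THZ1 libraries, at least 4.69-fold lower against a floor of 3 reads per library (limma adjusted p = 0.0043). Features of this kind lie inside other genes and the strand setting is not given, so reads of the unspliced host transcript cannot be separated from theirs.

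The rises were ranked among genes called in CAL-62 with a mean value of at least 5 and no overlap between the groups. The largest of these were in RN18S1, the 18S ribosomal RNA, and ARC, an immediate early gene best known from neurons. RN18S1 had 59 and 46 reads under DMSO and 758 and 980 after THZ1, or 1.25 ± 0.296 against 28.7 ± 0.945 (change 3.73, SE 0.25, limma adjusted p = 0.012). The RNA had been selected for poly(A), and the 18S RNA has no regular poly(A) tail. ARC rose from 1.03 ± 0.394 to 15.9 ± 7.20 (change 3.004, SE 0.37, limma adjusted p = 0.0227). TNFRSF10D, a decoy receptor for the death ligand TRAIL, rose from 8.16 ± 4.82 to 56.1 ± 30.8 (change 2.63, SE 0.48, limma adjusted p = 0.03). SAT1, which acetylates spermidine and spermine for export, rose from 43.8 ± 17.1 to 158 ± 30.2 (change 1.87, SE 0.29, limma adjusted p = 0.0224). The uncharacterised gene LOC100506168 rose from 9.01 ± 1.40 to 36.0 ± 16.6 (change 1.82, SE 0.33, limma adjusted p = 0.0304).

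Of 11362 genes tested in CAL-62, 525 were called in the main fit, 66 higher and 459 lower (87.4% lower), and each of the 525 had the same sign in both replicate numbers. The calls came from these same libraries, so that agreement is not independent evidence. A change of at least 2-fold was seen in 30 of the higher and 451 of the lower genes. Because genes with a DMSO mean under 1 are outside the table, rises from low levels are undercounted. With a replicate block within each line 4563 genes were called, 2503 higher and 2060 lower (45.2% lower). The labels do not say what the replicate numbers mark. Among fits that take no account of the replicate number, the share of lower calls depended on the scaling and the fit, at 79.5% of 609 calls with median-of-ratios scaling, 77.8% of 743 with limma-voom on recovered reads, 97.3% of 802 with upper-quartile scaling, 99.3% of 1491 with the sum of reads, 99.9% of 2916 with ribosomal protein genes as reference and 99.6% of 526 with mitochondrially encoded genes as reference. The count rested on the spread shared with BCPAP and on single libraries: 0 genes were called from the 4 CAL-62 libraries alone (3418 of the 11362 had an unadjusted p under 0.05 in the 8-library fit), 9 and 0 without CAL-62 DMSO replicate 1 or 2, 260 and 465 without CAL-62 THZ1 replicate 1 or 2, 186 and 181 without BCPAP DMSO replicate 1 or 2, and 811 and 806 without BCPAP THZ1 replicate 1 or 2 (64.4% and 64.6% of them lower).

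**Figure D1:**
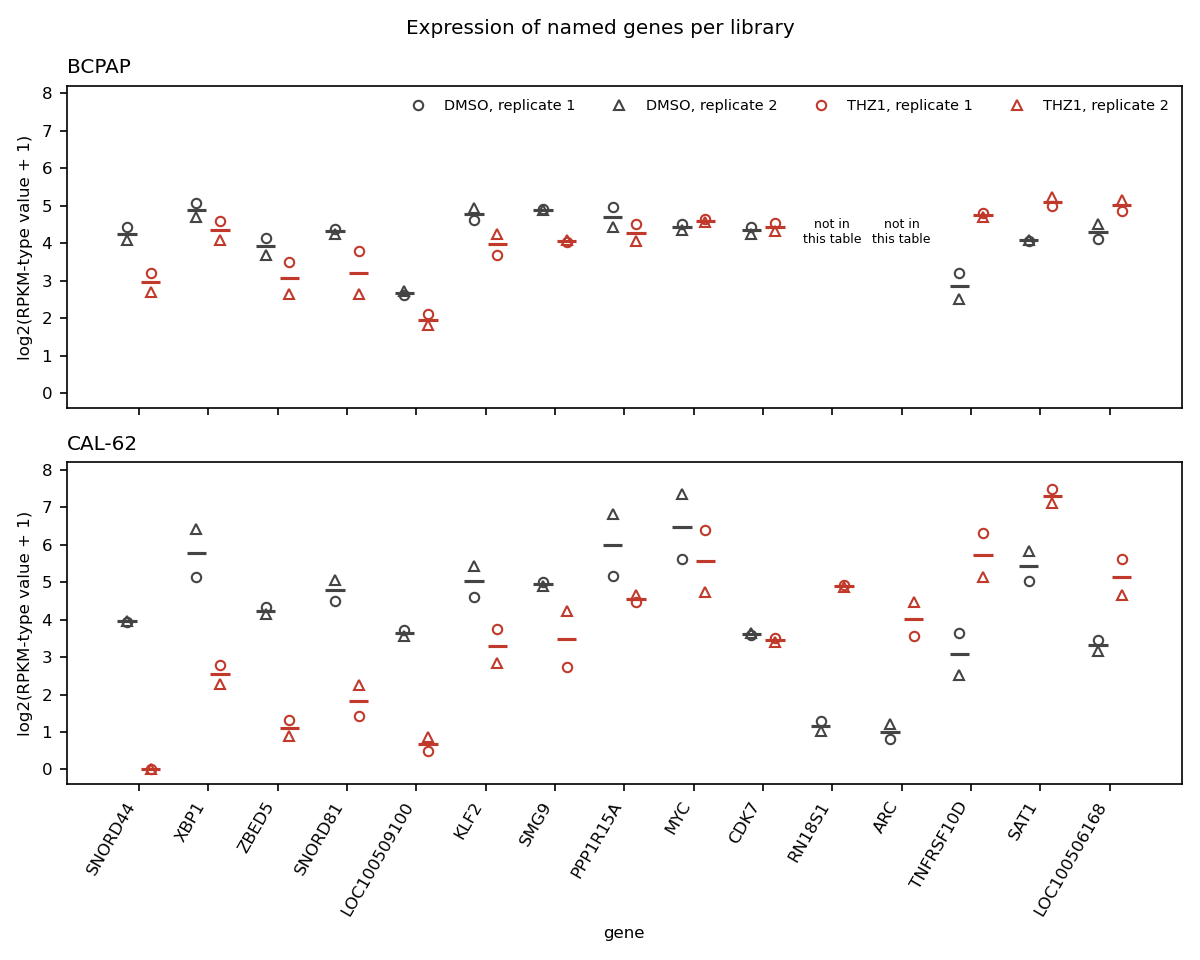
Values of 15 named genes per library on the log2(value + 1) scale, BCPAP above and CAL-62 below; circles are replicate 1, triangles replicate 2, grey DMSO, red THZ1, and each bar is the mean of 2 libraries. SNORD44 is at 0 in both CAL-62 THZ1 libraries, and MYC spreads widely between the CAL-62 replicates.

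Among the fixed gene lists, those of ribosomal proteins and of the nuclear-encoded respiratory chain had the smallest camera p-values in CAL-62. Both lists stood higher than other genes at the deposited scaling. All 74 ribosomal protein genes had a positive change at the deposited scaling (median 0.96, camera adjusted p = 4.23e-16), whereas the median turned to -0.0087 and -0.11 with ribosomal protein and mitochondrially encoded genes as reference. Of these, 3 were called higher over all genes and 48 adjusted over the list alone, with none lower, and adjusted p = 0.882 with an estimated correlation. RPL38 went from 138 ± 13.1 to 296 ± 15.4 (change 1.10, limma adjusted p = 0.0372), RPL37 from 168 ± 12.5 to 352 ± 49.6 (change 1.05, limma adjusted p = 0.0417), and the third called member was RPS24 (change 0.92, limma adjusted p = 0.0469). All 47 respiratory chain genes were likewise positive (median 0.87, camera adjusted p = 1.15e-15, and adjusted p = 0.882 with an estimated correlation), turning to a median of -0.079 and -0.17 with the same references. Of these genes, 2 were called higher over all genes and 41 adjusted over the list alone. COX6A1, a subunit of cytochrome c oxidase, went from 256 ± 6.72 to 509 ± 42.2 (change 0.99, limma adjusted p = 0.0438) and COX5B, another subunit, from 128 ± 1.69 to 246 ± 17.8 (change 0.94, limma adjusted p = 0.0469). Relative to the median of all genes, the ribosomal protein median lay between 0.71 and 0.93 over the 5 other scalings. The respiratory chain median lay between 0.645 and 0.84. A factor per library moves all genes nearly alike, so these relative values could hardly change and are no check on the scaling.

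The list of glycolysis and hypoxia genes also passed in CAL-62 (median 0.59, 19 of 25 positive, camera adjusted p = 0.0057), as did the 13 mitochondrially encoded genes (median 1.07, the highest of the lists, camera adjusted p = 0.026) and the 12 replication-dependent histone genes (median 0.74, camera adjusted p = 0.0399). With ribosomal protein genes as reference the medians were -0.31, 0.10 and -0.082, and with mitochondrially encoded genes -0.40, 0.0039 and -0.16. No member of these 3 lists was called, over all genes or adjusted over the list alone. With an estimated correlation the first 2 had an adjusted p = 0.882, and the histone list, with fewer than 5 members in both tables, had no such value. Histone mRNAs of this class mostly lack poly(A) tails, so their values rest on what the selection let through. The histone median was 1.14 within replicate number 1 and 0.33 within number 2.

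Lists without a passing set test held called genes of several kinds, almost all lower in CAL-62, as were 87.4% of all calls in the main fit. Over all genes 459 of 11362 were called lower, so a few called members do not make a result about a list. Of 29 DNA repair genes, 3 were called lower (5 adjusted over the list alone): the nuclease gene ERCC4 (change -1.24, limma adjusted p = 0.032), the exonuclease gene EXO1 (change -1.57, limma adjusted p = 0.0446) and XRCC2 of homologous recombination (change -1.89, limma adjusted p = 0.0292). Of 39 S-phase genes, 2 were called lower (1 higher and 2 lower adjusted over the list alone), the replication factor GINS1 (change -2.09) and the polymerase subunit POLD3 (change -1.61). Of 23 NF-κB and cytokine genes, the transcription factor IRF1 (change -1.42) and the inhibitor gene NFKBIE (change -1.04) were called lower (2 adjusted over the list alone). CCNF, cyclin F, was the 1 member called of 38 G2/M genes (change -1.75; 2 lower adjusted over the list alone). BAK1, a pro-apoptotic pore former, fell in the list of 17 death effectors (change -1.70), IFIT5 among 20 interferon genes (change -1.72) and the tight junction gene CLDN1 among 11 epithelial genes (change -1.21). Adjusted over the list alone, these 3 lists had 1 lower, 1 higher and 3 lower, and 1 lower.

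PAX8, a transcription factor of the thyroid lineage, was called lower among the 4 thyroid differentiation genes tested in CAL-62 (104 ± 18.5 to 17.5 ± 17.4, change -2.92, limma adjusted p = 0.0469). Its change was -3.89 within replicate number 1 and -1.94 within number 2. The 2 called genes that rose in this set of lists were SNAI1, a repressor of epithelial genes, among 22 mesenchymal genes (change 1.66, limma adjusted p = 0.029), and HSPE1, the mitochondrial co-chaperonin, among 20 heat shock genes (change 0.96, limma adjusted p = 0.0432), and each was also the 1 gene past the threshold adjusted over its list alone. HSPE1 turned to -0.04 with mitochondrially encoded genes as reference. XBP1 was the called member of 28 ER stress and ATF4 genes, of which 14 were positive and 14 negative (1 higher and 4 lower adjusted over the list alone). The median change was -0.61 over 9 survival genes of the BCL2 family (8 negative, camera adjusted p = 0.122), -0.49 over 24 p53 targets (17 negative, camera adjusted p = 0.122) and -0.33 over 24 MAPK output genes (15 negative, camera adjusted p = 0.229). None of the members of these last 3 lists was called over all genes; adjusted over the list alone, 1 p53 target was higher and 3 were lower.

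The fixed list of immediate early genes, which does not hold ARC, went opposite ways in the CAL-62 replicates. The median over its 31 tested genes was 0.92 within replicate number 1 and -1.01 within number 2, and none was called. The NF-κB and cytokine list likewise had medians of 0.31 and -1.10, and MYC changes of 0.78 and -2.62. Medians of the remaining lists in CAL-62 were -0.32 over 24 YAP/TEAD targets, -0.22 over 19 TGF-β response genes, 0.32 over 22 cholesterol genes and 0.16 over 26 genes of TFIIH and the transcriptional kinases. None of their members was called over all genes, and adjusted over the list alone 1 kinase-list gene was higher and 1 lower. For immediate early and G2/M genes the median change and the direction of the set test had opposite signs. Among marker lists of other cell types, 2 blood cell, 2 endothelial and 1 fibroblast gene were tested in CAL-62, with medians of 0.55, 0.61 and 0.34 and none called over all genes (1 blood cell gene higher adjusted over the list alone).

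In BCPAP the same treatment gave no gene past the threshold. Of 11743 genes, limma called 0 (smallest adjusted p 0.932), 471 had an unadjusted p under 0.05 where 587 were expected by chance, and limma-voom on recovered reads also called 0. TNFRSF10D had 6.46 ± 2.44 under DMSO and 25.8 ± 1.40 after THZ1 (change 1.88, SE 0.48), and SAT1 had 15.9 ± 0.154 and 33.8 ± 4.06 (change 1.04, SE 0.29). SNORD44 had 18.3 ± 3.38 and 6.85 ± 1.84 (change -1.31, SE 0.26), SNORD81 a change of -1.10, ZBED5 of -0.84, LOC100509100 of -0.71, XBP1 of -0.54 and LOC100506168 of 0.70. Each of these 8 had a limma adjusted p = 0.932 and the same sign in both replicate numbers. The simulation called 68% of 4-fold changes in BCPAP and 18% of 2-fold changes, so as simulated 2-fold changes would mostly have been missed. It changed only genes with many reads and drew noise independently for each library. Deviations of same-numbered BCPAP libraries correlated, however (r = 0.779), so these shares may not hold for the real libraries. Such a correlation can make p-values from a fit without a block too large. The count below chance therefore does not speak against a response.

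As lists, ribosomal protein genes (median 0.325, 73 of 74 positive, camera adjusted p = 1.28e-05), respiratory chain genes (median 0.31, 47 of 47 positive, camera adjusted p = 9.96e-07) and glycolysis and hypoxia genes (median 0.29, 27 of 30 positive, camera adjusted p = 0.017) stood higher in BCPAP than other genes. With mitochondrially encoded genes as reference the medians turned to -0.071, -0.076 and -0.10. Each had an adjusted p = 0.882 with an estimated correlation, and none of their members was called, over all genes or adjusted over the list alone. The first 2 rested largely on replicate number 2, with medians of 0.08 and 0.58 within numbers 1 and 2 for ribosomal proteins and 0.12 and 0.53 for the respiratory chain. Without BCPAP THZ1 replicate 2, the ribosomal protein median lay at -0.11 relative to the median of all genes. The other lists had no called member over all genes in BCPAP; adjusted over the list alone, 1 immediate early gene and 1 TGF-β response gene were higher.

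**Figure D2:**
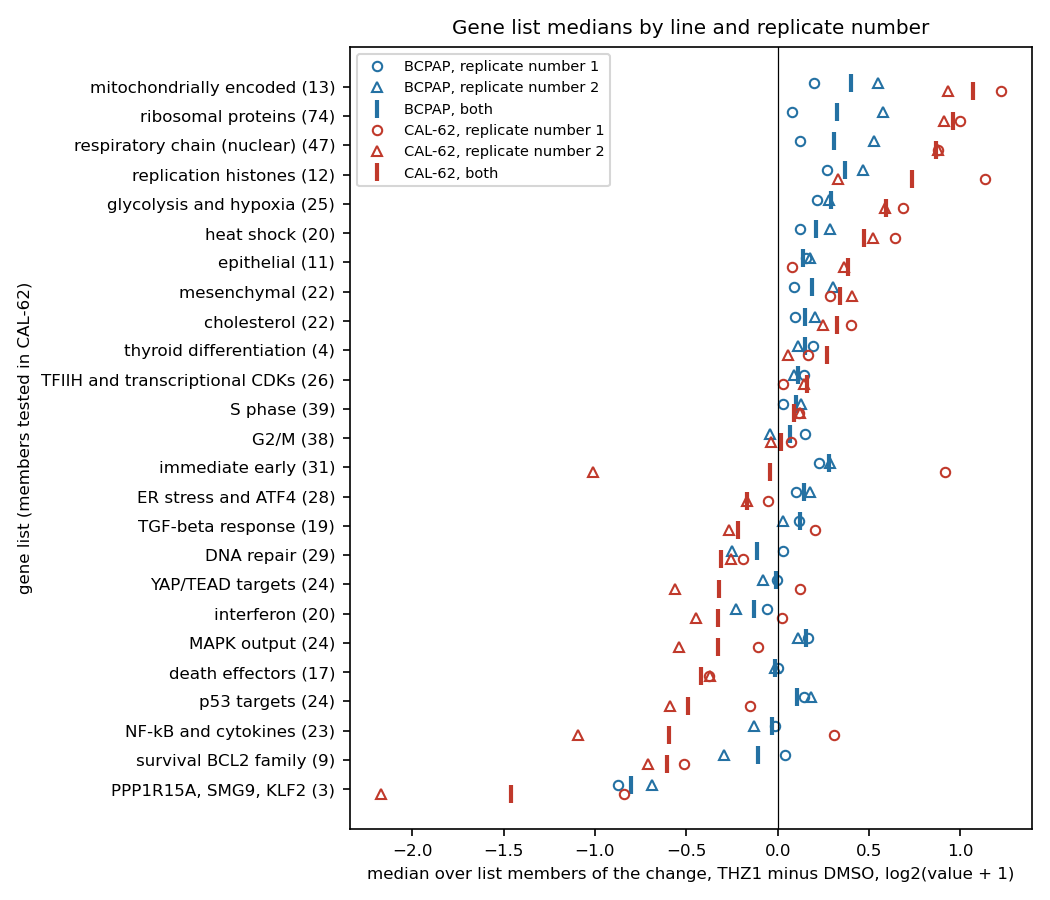
Median change after THZ1 over the members of each gene list with at least 3 tested members, in log2(value + 1); blue is BCPAP, red CAL-62, circles and triangles are replicate numbers 1 and 2, and bars both together. The CAL-62 immediate early median is 0.92 in number 1 and -1.01 in number 2, and the ribosomal protein medians are positive in both lines and both numbers at the deposited scaling, though not with mitochondrially encoded genes as reference (-0.071 in BCPAP and -0.11 in CAL-62).

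The kinases bound by THZ1 and the genes of interest to the study were examined in both lines. CDK7 had 19.5 ± 1.88 and 20.5 ± 2.29 in BCPAP (change 0.07) and 11.3 ± 0.365 and 10.0 ± 0.572 in CAL-62 (change -0.15, limma adjusted p = 0.639). CDK12 and CDK13, related kinases that THZ1 also binds, had changes of 0.04 and 0.19 in BCPAP and of -0.63 and -0.42 in CAL-62 (limma adjusted p = 0.192 and 0.451). None of these values passed in the main fit. With ribosomal protein genes as reference CDK12 passed in CAL-62 (change -1.55, limma adjusted p = 0.0418), and the BCPAP signs of all 3 turned. MYC had 20.5 ± 1.68 and 23.3 ± 0.961 in BCPAP (change 0.18, negative with either reference) and 105 ± 80.1 and 54.5 ± 41.1 in CAL-62 (change -0.92, limma adjusted p = 0.36). PPP1R15A, a phosphatase subunit of the stress response, SMG9, a factor of nonsense-mediated decay, and the transcription factor KLF2 had negative changes in both replicate numbers of both lines. In BCPAP the changes were -0.42, -0.83 and -0.80; in CAL-62 they were -1.43, -1.46 and -1.72, with limma adjusted p = 0.106, 0.0753 and 0.0522. Over all genes 0 of the 3 passed in either line in the main fit. Some alternatives called them in CAL-62 (all 3 with either reference, and KLF2 and SMG9 with some settings that keep the deposited scaling). PPP1R15A also passed there at the deposited scaling, with a replicate block within each line. Adjusted over the list alone 3 passed in CAL-62 and 0 in BCPAP. The study picked these genes on the same samples, so their direction here is not independent evidence.

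The responses of the lines ran in the same direction for most genes. Across 10653 genes tested in both, the changes correlated with r = 0.656 and rho = 0.666 (across genes, which are not independent replicates; the comparisons share no libraries). Of 510 genes called in CAL-62 and tested in BCPAP, 494 had the same sign there (96.9%, exact 95% interval 94.96 to 98.2%, which treats genes as independent), against 75.8% of all genes. The 446 called lower in CAL-62 had a median change of -1.52 there and -0.50 in BCPAP, where 431 were negative. The 64 called higher had medians of 0.97 and 0.40, and 63 were positive in BCPAP; choosing genes by their calls in CAL-62 favours larger changes there. Within replicate number 1 the lines' changes correlated with r = 0.554, and 458 of the 510 had the same sign in BCPAP; within number 2 the values were 0.585 and 498. Within a line, the changes of replicate numbers 1 and 2 correlated across genes with r = 0.596 in BCPAP and 0.665 in CAL-62.

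**Figure D3:**
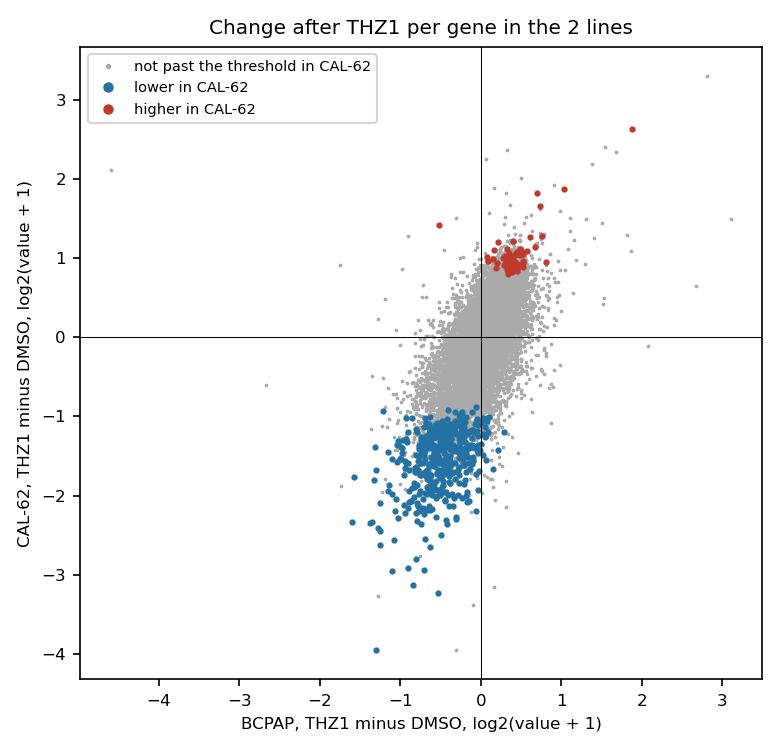
Change after THZ1 in BCPAP (horizontal) against CAL-62 (vertical) for 10653 genes in log2(value + 1), with genes called in CAL-62 in blue (lower) and red (higher). Of the 446 lower genes 431 lie left of 0, and of the 64 higher genes 63 lie right of 0.

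Although 525 genes were called in CAL-62 and 0 in BCPAP, a difference between the lines was not shown for any single gene. The test of the difference called 0 of 10653 genes (limma, smallest adjusted p 0.834; 562 had an unadjusted p under 0.05 where 533 were expected), and limma-voom called 0. By lists, the CAL-62 response exceeded that of BCPAP for ribosomal proteins (median difference 0.63, camera adjusted p = 1.15e-15), the nuclear-encoded respiratory chain (0.56, camera adjusted p = 2.16e-13), mitochondrially encoded genes (0.70, camera adjusted p = 0.0306) and glycolysis and hypoxia genes (0.33, camera adjusted p = 0.0384), in each case relative to other genes. With mitochondrially encoded genes as reference these median differences were -0.035, -0.097, 0.037 and -0.19. It lay below that of BCPAP for p53 targets (-0.59, camera adjusted p = 0.0285) and MAPK output genes (-0.40, camera adjusted p = 0.0306). All 6 had an adjusted p = 0.882 with an estimated correlation, and no member was called, over all genes or adjusted over the list alone.

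Under DMSO the largest called differences between the lines were in TGFBI, BASP1 and PLAT, higher in BCPAP, and in TPM2 and STMN3, higher in CAL-62. TGFBI, a matrix protein induced by TGF-β, stood at 1701 ± 275 in BCPAP and 4.16 ± 0.445 in CAL-62 (difference -8.36, SE 0.21, limma adjusted p = 2.5e-06). BASP1, a membrane-bound signalling protein, had 200.1 ± 11.8 and 2.68 ± 1.61 (difference -5.85, limma adjusted p = 2.68e-04). The plasminogen activator PLAT had 230.1 ± 39.3 and 3.64 ± 1.19 (difference -5.65), and the matrix glycoprotein THBS1 146 ± 19.5 and 3.34 ± 1.13 (difference -5.10). On the other side, tropomyosin TPM2 had 7.65 ± 0.00950 in BCPAP and 368 ± 25.7 in CAL-62 (difference 5.41, SE 0.20, limma adjusted p = 2.42e-05), and STMN3, a microtubule regulator, 1.46 ± 1.28 and 91.1 ± 0.659 (difference 5.33). The cytokine IL32 had 2.504 ± 0.547 and 100.6 ± 10.8 (difference 4.86), CENPV 1.37 ± 0.714 and 51.3 ± 5.50 (difference 4.49), and the secreted protease HTRA1 2.93 ± 2.26 and 71.3 ± 20.9 (difference 4.30).

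In total 1505 of 10653 genes differed between the lines under DMSO, 673 higher and 832 lower in CAL-62. Each had the same sign in both replicate numbers, which is not independent evidence, since the calls came from the same libraries. Of 22 mesenchymal genes, 5 were higher and 12 lower in CAL-62 (6 and 13 adjusted over the list alone), and of 25 glycolysis and hypoxia genes, 1 was higher and 13 were lower (1 and 19 adjusted over the list alone). Of 47 respiratory chain genes, 7 were higher and 0 lower (9 and 0 adjusted over the list alone), and of 20 interferon genes 0 were higher and 6 lower (0 and 7 adjusted over the list alone). Of 28 ER stress genes, 5 were higher and 2 lower (6 and 2 adjusted over the list alone). Only genes with a DMSO mean of at least 1 in both lines entered, so genes silent in either line are missing, and the 2 tables were scaled separately by the authors. The count was 311 and 288 without BCPAP DMSO replicate 1 or 2 and 393 and 283 without CAL-62 DMSO replicate 1 or 2, and 834 and 204 with ribosomal protein or mitochondrially encoded genes as reference. The balance turned with 2 scalings: 1000 were higher and 726 lower in CAL-62 with the sum of reads, and 586 and 248 with the ribosomal protein reference. With the mitochondrial reference lower genes stayed the majority, at 40 higher and 164 lower.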

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

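The 6 gene lists whose response differed between the lines in the set test, and 2 results that moved opposite ways in the lines, are taken up here. The patterns were noticed in the data, and what each explanation would show was written down before its test was run.

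The CAL-62 response exceeded the BCPAP response by a median of 0.63 over ribosomal protein genes, 0.56 over nuclear-encoded respiratory chain genes, 0.70 over mitochondrially encoded genes and 0.33 over glycolysis and hypoxia genes, on the log2 scale. It lay below by -0.40 over MAPK output genes and by -0.59 over p53 targets. What drew attention was the camera test of the difference itself, and none of the 6 passed with an estimated correlation (adjusted p = 0.882 each). That version rests on few residual degrees of freedom and has little power. It cannot show whether correlation between genes accounts for these results.

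The rise of ribosomal protein and respiratory chain genes in CAL-62 was weighed against length and expression level. At the deposited scaling, random lists matched to the ribosomal protein genes on both had a median of 0.74. The ribosomal protein genes had 0.96, above all 10000 (percentile 100.0). For the respiratory chain the median was 0.866 against 0.695 in its matched lists, the highest of which reached 0.874 (percentile 99.98). Matched genes thus shared much of the rise. The genes drawn for each list could include those of the other list, however, and the level used for matching included the THZ1 libraries. How far other short, abundant genes rose is therefore not given by these medians. By the prediction written beforehand, the ribosomal protein percentile counted against length and level. Quintiles match only coarsely, however: RPL38 stood at 138 in CAL-62 under DMSO, where the library medians were 9.86 and 9.81. The random lists also take genes as independent, so the test cannot decide whether length and level are the whole of it. A factor per library moves all genes alike, so scaling does not account for a rise over other genes. Whether the 2 lists rose in amount or other genes fell stays open. By the prediction written beforehand, a median at 0 or below with any scaling tried was to count for scaling as the cause. With 2 of the 5 scalings tried the median of either list turned to 0 or below, so the prediction as written came out for scaling. These 2 scalings hold level the ribosomal protein or the mitochondrially encoded genes, which rose as well at the deposited scaling. They therefore cannot decide between the 2 readings. A biological hypothesis is that long-lived mRNAs gain share when synthesis of short-lived ones falls under a CDK7 inhibitor, which may leave their amount per cell level, and without added standards these values cannot give amounts per cell.

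CDK7 had small changes of opposite sign in the lines (difference -0.22, limma adjusted p = 0.887), and its BCPAP sign turned with several scalings. The medians over ER stress and ATF4 genes were 0.10 and 0.18 within numbers 1 and 2 in BCPAP and -0.06 and -0.17 in CAL-62, with a median difference of -0.35 that did not pass (camera adjusted p = 0.101).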

How the results depend on the processing

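Some alternatives were chosen after the data were seen. These were 1 replicate block shared by all libraries, limma-voom with a replicate block, and leaving out features under 300 nt. The estimated correlation of the list tests with a replicate block was added later too. The plan already held the estimated correlation beside the preset one. The planned main test for counts, edgeR quasi-likelihood, was not run, and neither was DESeq2. The plan gave limma for normalized values, which the files hold. The recovered reads could have carried a count test, but they were used with limma-voom only. Unless a construction is named, the cause of a change was not tested. Reference scalings moved the median of all genes in CAL-62 by construction, to -0.77 with ribosomal protein and -0.81 with mitochondrially encoded genes, against 0.031; upper-quartile scaling gave -0.14 and the sum of reads -0.33. In BCPAP the reference scalings gave -0.21 and -0.29, against 0.067.

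The CAL-62 count of 525 was 802 with upper-quartile scaling, 1491 with the sum of reads, 2916 with ribosomal protein genes as reference, 196 at a mean of at least 5 (fewer genes tested) and 0 with only the compared libraries (fewer samples). It ranged from 0 to 811 when 1 library was left out, where the lone sample of a group is assumed to vary like the other groups; the other alternatives without a block gave 526 to 743. The BCPAP count of 0 became 2 with the mitochondrial reference and ranged from 0 to 1 without 1 library. The count of 0 for the difference of responses became 1 with the mitochondrial reference and 1 with a pseudocount of 0.1. The DMSO comparison of the lines, 1505, gave 834 with the ribosomal protein and 204 with the mitochondrial reference, and 283 to 1898 without 1 library. The 14 list tests past the threshold became 30 with the mitochondrial reference, 8 at a mean of at least 5, 0 with an estimated inter-gene correlation, and 10 to 31 without 1 library. The shared direction of 96.9% became 99.6% with the mitochondrial reference and ranged from 78.3 to 98.4% without 1 library, with no value without CAL-62 DMSO replicate 2, where no gene was called.

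The replicate numbers are shared by the groups, the labels do not say what they mark, and 2 numbers per group are too few to settle from the values whether they pair the samples. As a hint from the data, deviations of same-numbered libraries correlated in all 6 pairs of groups, with r = 0.779 between BCPAP groups, 0.464 between CAL-62 groups and 0.433 to 0.523 across the lines. With a replicate block within each line, CAL-62 had 4563 calls (2503 higher, 2060 lower, all 525 among them), with the shared replicate block 4045, and with limma-voom and a replicate block 4198; lower genes were 45.2%, 47.4% and 44.0% of these calls, so the majority of lower calls in CAL-62 did not hold with a block. BCPAP and the difference stayed at 0 in all 3. In CAL-62, CDK12 (limma adjusted p = 0.0226, 0.0249 and 0.0155), KLF2 and SMG9 passed with each of the 3, and PPP1R15A with all but the shared block. The DMSO comparison gave 3873 with the shared replicate block. The other 2 fits held a block within each line, so they compared the lines at replicate number 1 and not at the group means. Their 3001 and 2990 calls therefore cannot be set against the 1505 of the main fit. The shared direction was 91.7%, 92.4% and 92.1% with the 3 blocks, in the order above. List tests numbered 22 with limma-voom and a replicate block, and 0 with a replicate block and an estimated correlation.

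Signs of single results turned mainly with the reference scalings. With ribosomal protein and mitochondrially encoded genes as reference, in this order, the BCPAP changes were -0.26 and -0.35 for CDK12, -0.090 and -0.18 for CDK13, -0.23 and -0.31 for CDK7, and -0.13 and -0.21 for MYC. In CAL-62 they were -0.025 and -0.12 for COX5B and -0.048 and -0.14 for RPS24. With the mitochondrial reference alone, COX6A1 was -0.073, HSPE1 -0.036 and RPL37 -0.0066. CDK12 in BCPAP was -0.013 with median-of-ratios, -0.0745 with upper-quartile and -0.14 with sum-of-reads scaling, and CDK7 -0.039 and -0.10 with the latter pair. Without 1 library, BCPAP values ranged from -0.32 to 0.40 for CDK12, from -0.050 to 0.42 for CDK13, from -0.036 to 0.18 for CDK7 and from -0.11 to 0.65 for the relative ribosomal protein median, and CDK13 in CAL-62 from -0.93 to 0.10. Of 38 named gene results past the threshold, 38 kept sign and call with median-of-ratios scaling and with no filter, 37 with a pseudocount of 0.1, and 9 without CAL-62 DMSO replicate 2. Without a block, CDK12 gained a call in CAL-62 with the ribosomal protein reference; PPP1R15A with both reference scalings (adjusted p = 0.0147 and 0.0481); SMG9 with these (0.0089 and 0.0495), the sum of reads (0.0344) and without CAL-62 THZ1 replicate 2 (0.0265); and KLF2 with 9 alternatives, at adjusted p-values from 0.0063 to 0.0491. Depth limits small RNA features most, at a median of 12 DMSO reads per small nucleolar RNA in CAL-62.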

Other observations

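The tests of read number and of carry-over for the small nucleolar RNAs were chosen after the result was seen. A different test of read number, on the called features alone, had been written down beforehand, and its outcome is not reported here. Zinc finger genes made up 72 of the 459 genes called lower in CAL-62. Of 341 tested genes named ZNF, most of them sequence-specific DNA-binding factors, these 72 were called lower and 0 higher (21.1% against 3.51% of other genes; Fisher's exact test, two-sided, adjusted over 4 gene groups, p = 6.32e-32, with genes taken as independent). Their median change was -0.82, with 310 of 341 negative, and -0.64 and -1.09 within replicate numbers 1 and 2. In BCPAP, where no gene was called, the median over 318 of them was -0.15 and 215 were negative. The median lay below those of all 10000 random lists matched on length and mean level (percentile 0.00), which centred on -0.22, so genes named ZNF may respond more than other genes of their length and level, a hypothesis from the same CAL-62 values in which the group was noticed.

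Protein-coding genes annotated with a single exon also fell. Of 180 tested in CAL-62, 31 were called lower and 0 higher (17.2% against 3.68% of the rest; Fisher's exact test, two-sided, adjusted over the same 4 groups, p = 4.70e-12). The median change of the 179 with a recovered length was -0.57, below all 10000 matched lists of multi-exon genes (percentile 0.00), which centred on -0.03. Single-exon genes may thus respond more than multi-exon genes, a hypothesis from the data on which it was tested. Short mRNA half-lives are a candidate explanation for both groups and were not tested, since half-lives were not used here.

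Small nucleolar RNA features were called lower in CAL-62 in 23 of 160 cases and higher in 0 (14.4% against 3.89% of the rest; Fisher's exact test, two-sided, adjusted over the same 4 groups, p = 1.45e-07). The group was noticed in these same CAL-62 values, so this p-value is not independent evidence. Of 72 microRNA features (named MIR), 6 were called lower and 0 higher (adjusted p = 0.0703). Few reads are argued against as the whole cause: the 80 of the 160 features with more reads, 29 to 565 over the 4 CAL-62 libraries, had a median change of -1.04, with 71 negative (exact 95% interval 79.7 to 94.7%, which treats features as independent), and medians of -0.61 and -1.30 within replicate numbers 1 and 2. Reads of the spliced host transcript are argued against too: the snoRNA changes lay below those of their hosts in 60 of 66 hosts, and the hosts had a median change of 0.74. The median difference was -1.02 and the mean difference -1.09 (two-sided sign-flip permutation test of the mean, p = 2e-05, the smallest it can give, with hosts taken as independent). A lower carry-over of all unpolyadenylated RNA after THZ1 is argued against as well, because 21 other RNAs that mostly lack poly(A) tails (12 histone mRNAs and 9 ribosomal or small RNAs) had a median of 0.82 relative to the median of all genes, with 20 above it. What stays open is whether the reads come from unspliced host transcripts, which could fall when transcription is inhibited, or from the small RNAs themselves; gene-level values do not decide this.

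All 4 groups split by replicate number, and the labels name no batch. Removing a smooth trend on GC content from each library left the same-number deviations correlated, at 0.34 in CAL-62 and 0.72 in BCPAP, and removing one on length left 0.44 and 0.78, so neither property alone accounts for the split. A shared day of culture or library preparation may explain it and was not tested, and no biological explanation was tested.

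RN18S1 was listed in the CAL-62 table only, where both THZ1 libraries had 758 and 980 reads against 59 and 46. Of the 12 tested histone genes, which are also RNAs that poly(A) selection mostly removes, 9 had positive changes in both CAL-62 replicate numbers, though the list median was -0.082 and -0.16 with the ribosomal protein and mitochondrial references.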
